A study of Caenorhabditis elegans with 2 samples.

How the data were processed

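Chromatin immunoprecipitation sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans larvae of 1 strain in 2 biological replicates, which form 1 group. Per the labels, the animals carried an integrated transgene encoding C04F5.9 with a C-terminal GFP-FLAG tag, were hermaphrodites at the first larval stage (L1), had been synchronised by bleaching and starvation and were collected 6 hours later. The immunoprecipitation used an antibody against GFP, and chromatin was fragmented by sonication, per the labels. The replicate numbers came from the labels. There was no second condition, so the comparisons were between the replicates and between the peaks and the genome.

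The values used here are the authors' lists of regions. For each genome assembly, ce10 and ce11, there was a list per replicate, a list from both replicates combined, and an optimal list thresholded by the irreproducible discovery rate (IDR), a measure of how well ranks agree between replicates. Per the file headers and companion text, regions in the relaxed lists were called on aligned reads against a control alignment as input for IDR. The aligner, the caller, their versions and the IDR cutoff are not given in the sources used here. Each region carries a signal value deposited by the authors, whose scale is set by the calling run. Signal was therefore used only to rank and describe peaks within a list. Each region also carries a −log10 q value deposited by the authors, which was 2.93 in every peak of the optimal ce11 list and so did not order them. The summit offset deposited by the authors gave the summit position. All 1205 regions of the optimal ce11 list were the 1205 highest-signal regions of the combined list. The number of reads behind each list is unknown, so no interval that needs depth is given. Control alignments and coverage tracks were not analysed here.

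The ce11 lists were the main data, since the genome sequence and the Ensembl release 115 annotation used here are of that assembly. All ce11 regions lay inside the chromosomes of that sequence. The ce10 lists were used only for counts, shares of chromosomes and overlap among themselves, and coordinates were never converted. Only the 6 nuclear chromosomes were used, with 19973 protein-coding genes. A promoter peak was one with its summit within 500 bp of an annotated transcript 5′ end of a protein-coding gene, and that gene was called a target gene. This assigns a gene by distance only.

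The tests below were fixed before the data were examined. The split at the 10 strongest peaks, the rank correlation of the replicates, the GC content, the annotation of summits and their position relative to 5′ ends were described after the data had been seen. Overlap of the top-ranked regions between replicates (at least 1 bp) was compared with 1000 random placements of the replicate 2 regions on the same chromosomes in a one-sided permutation test. The promoter share was compared with 1000 uniform placements on the same chromosomes in a two-sided permutation test, and by Fisher's exact test with combined-list regions that overlapped no optimal peak. The shares of peaks on chromosome X and in the third of each autosome around its centre were compared with shares of protein-coding genes by two-sided exact binomial tests. The same test on the other chromosomes was added after the data were examined. Target genes were tested against 40 gene lists, defined by gene symbol before the data were examined, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Words of 8 bases (8-mers, both strands collapsed) were compared between 50 bp each side of the summit and flanks 200 to 250 bp away by an exact sign test, for words present in at least 20 peaks. The summit window holds 94 word positions and the flanks 86, which favours the summit slightly. Genes and peaks, not animals, are the units of these tests, and neighbouring genes can share a peak, so the p-values describe the lists and not variation between cultures. Intervals are exact 95% binomial intervals for shares and 95% intervals for sample odds ratios, and cover counting error only.

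Genes named in the text followed a rule fixed before the data were examined. They are the genes at the 25 optimal peaks with the highest signal, the tagged gene C04F5.9, the strain marker unc-119, and up to 4 members with the strongest peaks of each list that passed its test. Peaks without a 5′ end within 500 bp were described by the nearest gene. Alternatives covered promoter windows of 250 and 1000 bp, the 602 peaks with the highest signal, each replicate alone, merging of summits within 200 bp, other backgrounds, words of 6 and 7 bases, and a 40 kb window at the tagged gene.

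The list test was tested on simulated targets at a base rate of 6%. In the first draw it recovered 3 of 5 lists planted at 4-fold odds. Only lists with at least 40 members were planted. Over 40 further draws it recovered 63.4% of planted lists with under 60 members, 91.0% of those with 60 to 99 and 100% of larger ones. A small list that missed the threshold therefore says little, and recovery of lists with under 40 members was not measured. Among 1270 tests of lists without planted genes, 3 were called. Simulated targets were drawn gene by gene, so false calls from neighbouring genes that share a peak were not measured. In 20 simulations the 8-mer test recovered the planted word in all 20, and called 158 shifted copies of it and 6 unrelated words. Without a planted word it made 1 call in 20 simulations. Summit and flank windows had the same base composition in these simulations, unlike in the data. They therefore say nothing about calls that arise from a difference in GC content. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.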

Results

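Binding of C04F5.9, annotated as a protein with a C2H2-type zinc finger domain, was measured by ChIP-seq against its GFP tag in whole L1 larvae, in 2 biological replicates. The authors' optimal list in ce11 held 1205 peaks, drawn from relaxed lists of 30000 regions in replicate 1, 28005 in replicate 2 and 30000 in both combined. The optimal list in ce10 held 1634 peaks. Read depth is unknown. Signal values are the authors' own and are compared only within a list.

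Signal was concentrated in very few promoters. The 10 strongest of the 1205 peaks held 48.3% of the summed signal, from 29681 down to 3152, against a list median of 114.9. The number 10 was chosen after the values were seen. All 10 had the same rank in replicate 1, replicate 2 and the combined list. Each lay within 500 bp of the 5′ end of a protein-coding gene.

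The strongest peak (chromosome IV, 1093959 to 1094797, ce11; signal 29681) lay between Y55F3AR.2 and cct-8, which encodes a subunit of the cytosolic chaperonin. Its summit was 179 bp upstream of the Y55F3AR.2 5′ end and 442 bp upstream of the cct-8 5′ end. The next (chromosome II, 10868560 to 10869356; signal 25161) lay between gmps-1, encoding GMP synthase, and cap-2, encoding an actin capping protein. The peak at rank 3 (chromosome I, 9619608 to 9620429; signal 22756) lay between nra-2 and lin-53, which encodes a histone-binding protein. Rank 4 was at Y25C1A.8 (chromosome II, summit 3077115; signal 22458). Rank 5 was shared by mig-5, encoding a Dishevelled protein, and cct-1, another chaperonin subunit (chromosome II, summit 8185207; signal 21100). Rank 6 was at lin-9 (chromosome III, summit 8904287; signal 19199), and rank 7 at sec-24.1, encoding a coat protein of vesicles that leave the endoplasmic reticulum (chromosome IV, summit 11566350; signal 14869). Ranks 8 to 10 were at ceh-38 and malt-1 (signal 8591), tag-353 (signal 5291) and T14G11.1 (signal 3152). The summit at rank 8 fell in the 5′ UTR of ceh-38, those at ranks 7 and 9 in annotated non-coding genes, and the other 7 were intergenic.

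Ranks 11 to 25 ran from 2557 down to 606.5. Rank 11 was shared by hsr-9 and the ribosomal protein gene rps-19. The others lay at F22D6.8 and F22D6.9, rbg-3 and rps-0, F31E3.6, fbxl-2, prpf-4 and ekl-1, rfc-4 and eef-1A.1, copz-1 and cyn-4, rpl-3, rpl-35, tasp-1, cdc-48.1, and rpl-15 and K11H12.8. Rank 13 had no 5′ end within 500 bp: its summit lay in the 3′ UTR of ekl-1, 1206 bp downstream of the 5′ end of F22D6.8. The 2 peaks at F31E3.6 held ranks 15 and 16. The second, a narrow peak, overlapped a region at rank 18 in replicate 2 and one at rank 1485 in replicate 1. The summits at ranks 12, 13 and 15 lay within 100 bp of near-identical copies of a single sequence, described below.

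**Figure D1:**
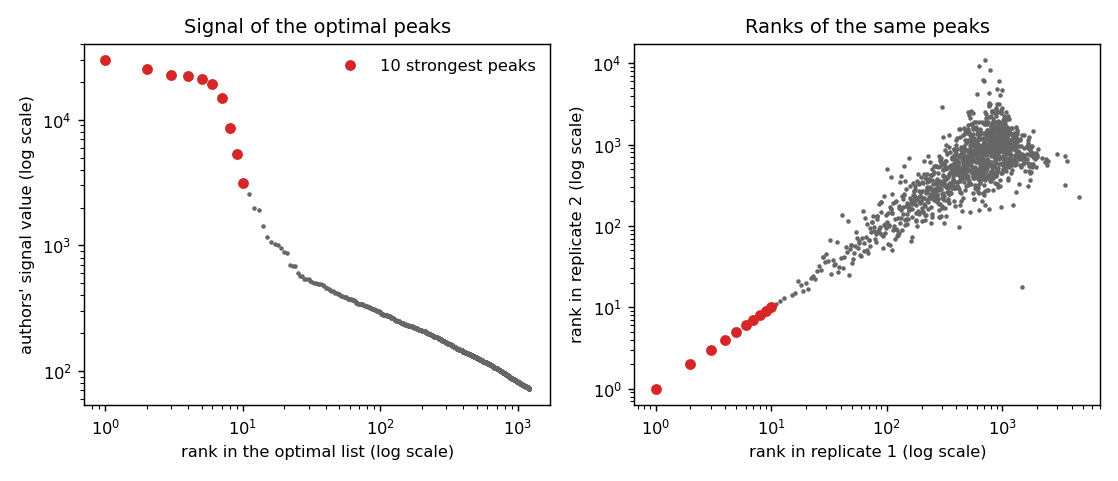
Left, the authors' signal value of each of the 1205 optimal peaks against its rank, both on log scales; right, the rank of the overlapping region in replicate 1 against that in replicate 2 for the 1201 peaks found in both. The 10 strongest peaks (red) range from 29681 to 3152 and lie on equal ranks, and weaker peaks scatter more.

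The question of reproducibility was addressed by comparing the replicates. Of the 1205 top regions of replicate 1, 885 overlapped one of the 1205 top regions of replicate 2 (73.4%, 95% interval 70.9 to 75.9%). Random placement gave a mean of 12.1 and at most 25 (one-sided permutation p = 0.001, the smallest 1000 placements can give). The share was 82.0% for the top 100, 76.6% for the top 500, 68.5% for the top 2000 and 54.2% for the top 5000. Across the 1201 optimal peaks found in both replicates, Spearman's rho of the signal values was 0.704. The optimal list had itself been selected for rank agreement between these replicates, so this value describes the selected peaks and is no separate measure of agreement.

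Peaks lay mostly just upstream of genes. Of the 1205 optimal peaks, 818 (67.9%, 95% interval 65.2 to 70.5%) had a summit within 500 bp of a protein-coding gene's 5′ end, and 740 of these 818 summits were upstream of it. The median position was -151 bp, with quartiles of -246 and -68.3 bp. Uniform placement on the same chromosomes gave 22.9% (two-sided permutation p = 0.002, the smallest possible). Among 28481 weaker regions of the combined list the share was 29.1% (odds ratio 5.15, 95% interval 4.55 to 5.83; Fisher's exact p = 2.04e-162). Summits in coding exons made up 1.24% of optimal peaks and 21.5% of 2000 weaker regions drawn at random. A single gene was assigned to 521 peaks and at least a pair to 297, giving 1101 target genes.

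**Figure D2:**
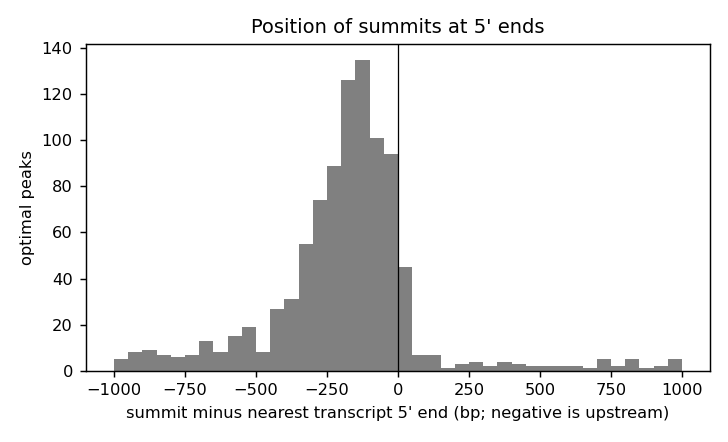
Number of optimal peaks by the distance in bp from the summit to the nearest protein-coding transcript 5′ end, in 50 bp bins up to 1000 bp on either side, negative values being upstream. Most summits lie upstream of the 5′ end, around the median of -151 bp for those within 500 bp.

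With the 500 bp window, the ribosomal protein list had the highest odds ratio. Of 79 ribosomal protein genes, 45 were targets (odds ratio 23.6, 95% interval 15 to 37; exact adjusted p = 1.6e-34), led by rps-19 (rank 11), rps-0 (rank 14), rpl-3 (rank 21) and rpl-35 (rank 22). With a 250 bp window the odds ratio was 3.80 (exact adjusted p = 0.0022), lower than those of 10 other enriched lists, among them translation factors (10.5), proteasome subunits (8.39) and the respiratory chain list (8.26). It was 13.5 when only the nearest gene of each peak counted. At 500 bp the respiratory chain and ATP synthase list counted 19 of 46 (odds ratio 12.3), with cox-5A, cox-5B, atp-1 and cox-6B, and translation factors 16 of 42 (odds ratio 10.7), including eef-1A.1, iff-2, eif-3.C and eif-3.B. Mitochondrial ribosomal proteins counted 14 of 66 (odds ratio 4.66), led by mrpl-28, mrpl-55, mrpl-18 and mrps-35. Over all protein-coding genes, 5.51% were targets.

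Protein folding, secretion and turnover were enriched as well. Of 43 genes listed under secretion through the endoplasmic reticulum and the unfolded protein response, 14 were targets (odds ratio 8.37), led by sec-24.1, sec-61.G, sec-61.B and trap-3. The last 2 shared a peak (rank 99). This and the other lists follow gene symbols, so they can hold genes of other functions. Chaperones counted 16 of 60 (odds ratio 6.31), with cct-8, cct-1, hsp-90 and dnj-9. Proteasome subunits counted 9 of 33 (odds ratio 6.47), with rpn-3, pbs-7, rpn-11 and pas-4. Small GTPases and vesicle traffic counted 15 of 91 (odds ratio 3.42), with copz-1, vps-51, apb-1 and rab-18.

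Nuclear functions formed a further group. Chromatin regulators counted 20 of 95 (odds ratio 4.64). Their strongest members were lin-53, lin-9 and lin-54, whose products belong to the DRM complex that represses transcription, and set-16. The lin-53 peak was shared with nra-2, whose 5′ end was slightly nearer (227 against 240 bp). The lin-54 peak was shared with a ribosomal protein gene, whose 5′ end was nearer (47 against 346 bp). Splicing factors counted 12 of 46 (odds ratio 6.11), with rsp-2 and rsp-1, which shared a peak (rank 227), snr-4 and prp-40. The list of RNA polymerase II, TFIID and Mediator genes counted 12 of 51 (odds ratio 5.32), with rpb-11, mdt-18, rpb-3 and mdt-1.2. DNA replication and cell cycle genes counted 13 of 61 (odds ratio 4.69), with cdc-48.1, pcn-1, mcm-10 and cdc-6. The exact adjusted p was 1.4e-11 for the respiratory chain list, and between 2.8e-09 and 0.00034 for the 10 other lists from translation factors to this point. With a 250 bp window the odds ratio was 3.45 for chaperones and 3.92 for splicing factors, and with the nearest gene of each peak only it was 3.18 for the RNA polymerase II list. The chaperone call was lost when only the nearest gene of each peak counted (odds ratio 2.17, exact adjusted p = 0.164), and the vesicle traffic call in the 602 peaks with the highest signal (exact adjusted p = 0.053).

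The 2 remaining enriched lists were close to the threshold. Cytoskeleton genes counted 8 of 62 (odds ratio 2.55, exact adjusted p = 0.040), with cap-2, tba-2, dnc-3 and dli-1, and vacuolar ATPase genes 4 of 21 (odds ratio 4.04, exact adjusted p = 0.049), with vha-8, unc-32, vha-12 and vha-9. Both lost the call when target status was rotated along the gene order (exact adjusted p = 0.083 and 0.114), in the 602 peaks with the highest signal (exact adjusted p = 0.216 and 0.226) and when only the nearest gene of each peak counted (exact adjusted p = 0.175 and 0.097). Both also depended on replicate 1: without it the odds ratios were 1.84 and 2.86 (exact adjusted p = 0.222 and 0.163). For cytoskeleton genes the odds ratio was 3.88 with a 250 bp window. The vacuolar ATPase call was lost with windows of 250 bp (odds ratio 1.30, exact adjusted p = 0.843), 1000 bp (exact adjusted p = 0.091) and 1000 bp upstream to 100 bp downstream (exact adjusted p = 0.073). With only the 7544 genes near a combined-list region as background, 9 of the 14 enriched lists passed, with lower odds ratios: ribosomal proteins 9.76, respiratory chain 5.94, translation factors 4.51, endoplasmic reticulum 3.76, chaperones 3.38, splicing 3.22, RNA polymerase II 2.95, chromatin 2.63 and mitochondrial ribosomal proteins 2.58. The proteasome (2.52), vacuolar ATPase (2.13), cell cycle (2.07), cytoskeleton (1.74) and vesicle traffic (1.58) lists did not pass (exact adjusted p between 0.080 and 0.383).

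Genes for sensing the environment and for defence were under-represented. Of 1310 chemoreceptor genes, 3 were targets (sri-5, srh-2 and srh-16; odds ratio 0.037, exact adjusted p = 1.1e-27). The F-box, BATH and MATH families counted 3 of 432 (fbxb-85, fbxb-72 and bath-36; odds ratio 0.117), and innate immunity and lectin genes 2 of 365 (fipr-17 and clec-126; odds ratio 0.093). Nuclear hormone receptors counted 4 of 274 (nhr-66, nhr-142, nhr-47 and nhr-57; odds ratio 0.251), and neuropeptides and insulins 1 of 144 (nlp-4; odds ratio 0.119). Molting and apical matrix genes counted 0 of 131. Exact adjusted p-values of these 5 lists were between 5.6e-07 and 0.011. With genes near a combined-list region as background the odds ratio was 0.115 for chemoreceptors, 0.229 for the F-box families and 0.208 for innate immunity, each still past the threshold (exact adjusted p = 3.4e-06, 0.014 and 0.038). Over all alternatives it ran from 0.037 to 0.115 for chemoreceptors, 0.071 to 0.231 for the F-box families, 0.070 to 0.208 for innate immunity and 0 to 0.286 for neuropeptides. In the 602 peaks with the highest signal the neuropeptide and molting calls were lost (exact adjusted p = 0.055 and 0.075), and the neuropeptide call also with a 250 bp window (exact adjusted p = 0.088), the nearest gene only (exact adjusted p = 0.072) or genes near a combined-list region as background (exact adjusted p = 0.086). Detoxification enzymes counted 4 of 223 (gst-27, dhs-1, gst-43 and dhs-2; odds ratio 0.311, exact adjusted p = 0.023), a call lost in the rotation (exact adjusted p = 0.065), in the 602 peaks with the highest signal (exact adjusted p = 0.098), with the nearest gene only (exact adjusted p = 0.080) and with genes near a combined-list region as background (exact adjusted p = 0.074).

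**Figure D3:**
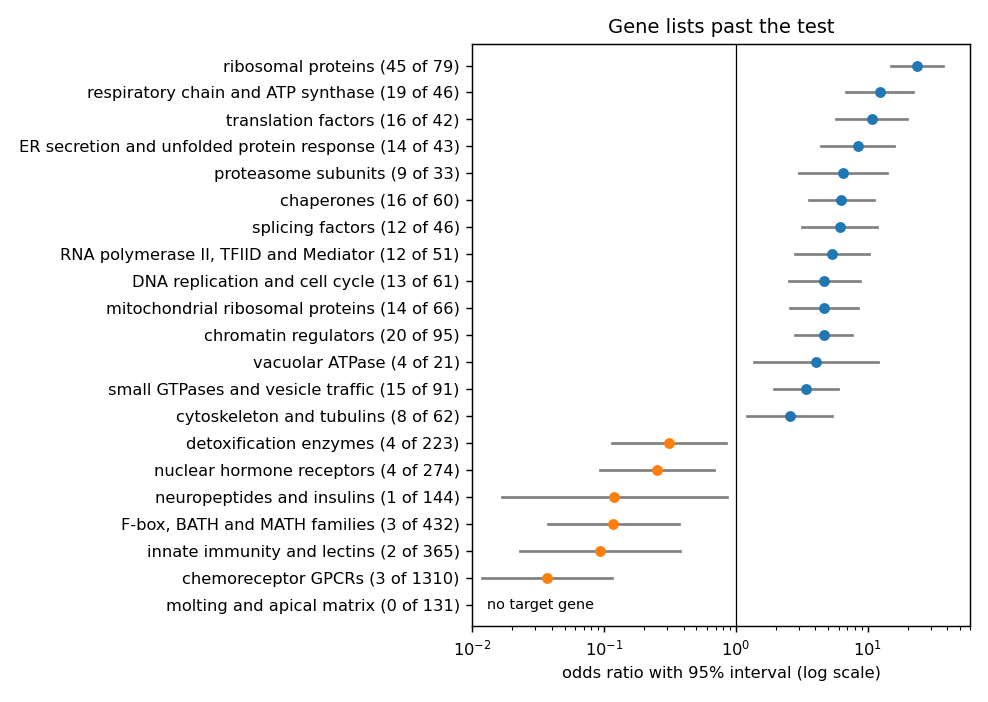
Odds ratio (log scale) for genes of each list to be targets, with the 95% interval as a line and the target and list counts in the labels, for the 21 lists past the test. The 14 enriched lists (blue) reach 23.6 for ribosomal proteins, and the depleted lists (orange) reach 0.037 for chemoreceptors; molting and apical matrix genes had no target and no interval.

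The other 19 lists did not pass. Aminoacyl-tRNA synthetases counted 5 of 32 targets, autophagy and lysosome genes 7 of 60, glycolysis and TCA cycle genes 4 of 42 and core and linker histones 6 of 81. Of fatty acid and lipid metabolism genes, 5.36% were targets. Among tissue lists, cuticle collagens counted 4 of 176, hypodermis and seam 1 of 84, intestine 0 of 32, body wall muscle 1 of 38, pharynx 4 of 91, synaptic and neuronal genes 1 of 51, germline 3 of 76 and sperm proteins 2 of 85. Homeobox factors counted 1 of 95, bHLH factors 1 of 37, zinc-finger and Kruppel-like factors 3 of 68 and GATA factors 0 of 12. Kinase and growth signalling genes counted 3 of 67, and Wnt and Notch signalling genes 1 of 38. Exact adjusted p-values of these lists were between 0.053 and 1.

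Peaks were unevenly spread over the chromosomes. Chromosome X held 138 of the 1205 peaks (11.5%, 95% interval 9.71 to 13.4%) and 13.7% of the protein-coding genes (exact binomial p = 0.024). The difference was no longer past the threshold with replicate 1 alone (11.9%, exact p = 0.071) or in the ce10 list (12.3%, exact p = 0.113). Of the 1067 autosomal peaks, 460 (43.1%, 95% interval 40.1 to 46.1%) lay in the third of the chromosome around its centre, against 38.1% of autosomal genes (exact binomial p = 0.00083). In the 602 peaks with the highest signal the central share was 41.7% (exact p = 0.092).

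Sequence at the summits differed from the flanks. GC content averaged 46.6% within 50 bp of the summit and 35.5% in the flanks, and was higher at the summit in 1015 of 1205 peaks. Of 1703 8-mers tested, 325 were enriched at the summit and 288 in the flanks. The first was AGACGCAG, present only at the summit in 111 peaks and only in the flanks in 7 (exact adjusted p = 5.8e-22), followed by the overlapping words GAGACGCA (106 against 6) and GACGCAGA (99 against 8), and then by GCAAACAC (84 against 6). Many of the 325 words overlap one another. Against weaker regions matched for GC content, 304 words were enriched, of which 240 were among the 325, and 25 were depleted. Of 140 words found on chromosomes I to III, 94 passed the same test on IV, V and X. Both sets used the same contrast with flanks, so this does not separate the words from GC content. The weaker regions were not matched for the share of promoters.

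No region of any ce11 list lay within 20 kb of C04F5.9, the tagged gene (chromosome V, 5114715 to 5119209). The gene lay in a stretch of 70.9 kb without a region in the combined list. At unc-119, the marker gene of the strain (chromosome III, 10902641 to 10908935), the combined list had 27 regions within 20 kb, the best at rank 2287, and none was an optimal peak. Within 40 kb of C04F5.9 the combined list had 2 regions.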

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

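The replicate overlap and the promoter share kept their direction and their side of the threshold under each alternative run, with overlaps of 68.2 to 76.4% and promoter shares of 50.5 to 81.0%. The optimal list held 1205 peaks in ce11, 1634 in ce10 and 1199 after merging of summits within 200 bp. The share on chromosome X was 11.4 to 11.9% when either replicate was left out, the upper value no longer past the threshold, and 12.3% in the ce10 list. Among the 602 peaks with the highest signal, 41.7% of the autosomal ones lay in the third around the centre, no longer past the threshold, with fewer peaks tested. Those peaks gave 4 depleted lists in place of 7. With genes near a combined-list region as background, an alternative chosen after the data were seen, 9 lists were enriched in place of 14. The odds ratio of the ribosomal protein list fell from 23.6 to 3.80 with a 250 bp window, 13.5 with the nearest gene of each peak and 9.76 with that background, and stayed past the threshold. The 250 bp window passes over the strongest peaks at rps-19, rps-0, rpl-3 and rpl-35, with summits 273 to 456 bp upstream. It keeps those at some other members. Without replicate 1 the cytoskeleton and vacuolar ATPase calls were lost (odds ratios 1.84 and 2.86). The number of enriched words moved with the number tested: 103 in the 602 peaks with the highest signal, 535 for 6-mers, 702 for 7-mers and 90 within 25 bp of the summit. A sign test that allows for the larger number of word positions at the summit, also chosen after the data were seen, gave 317. Words enriched in the flanks numbered 288, against 222 without replicate 1, 187 without replicate 2 and 408 in that sign test. Against weaker regions matched for GC content, 25 words were depleted. A 40 kb window found 2 combined-list regions at C04F5.9 in place of 0. The cause of these changes was not tested unless stated. Read depth is unknown, so its effect on weak peaks could not be assessed.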

Other observations

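Chromosomes other than X also differed, a comparison not planned before the data were examined. Chromosome III held 21.8% of the optimal peaks and 13.2% of the protein-coding genes (exact binomial adjusted p = 7.6e-16), and chromosome I 21% and 14.4% (exact adjusted p = 1.3e-09). Chromosome V held 11.8% and 25% (exact adjusted p = 1.7e-29). That is 99.6 peaks per 1000 genes on chromosome III and 28.4 on chromosome V. Chromosomes II and IV did not pass (exact adjusted p = 0.304 and 0.371).

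Of the tests below, those of the shared sequence of the strongest peaks and of the stretch at the tagged gene were chosen after the data were seen, as were the checks with a stricter threshold, with ranks held fixed, with copies grouped and with GC content matched. The first tests on ribosomal protein genes were set down before their results were known.

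The 10 strongest peaks appeared to share a long sequence, fitted here as 46 bp. The commonest base was the same in all 10 peaks at 5 positions and in at least 8 peaks at 20 positions. Most but not all of these lay among the first 20 positions, which read GGGTCTCGCAGCGATTTGCC. Within that stretch, positions 9 to 11 were held by only 5 or 6 peaks. Many later positions were held by 3 to 6 peaks. Both the number of peaks and the width were chosen after the sequences had been looked at. When each peak was left out of the fit and scored, 7 of 10 scored above all 28481 weaker regions, while ranks 5, 8 and 10 did not. Copies of one repeat cannot be excluded for these 10. Identity beyond both ends averaged 26.4%, against at most 30.3% in draws of other peaks, but the width had been chosen to cover the part that looked alike, so this value says nothing against a short repeat of about that length. Whether the sequence may mark binding sites elsewhere stays open. Of the 20 best genomic matches away from these peaks, 8 had their centre within 100 bp of an optimal summit. However, 7 of those 8 were near-identical copies of a single sequence. That leaves 2 of 9 distinct sequences, against at most 1 for matrices with shuffled positions. In the counts below, a match had to lie wholly within 100 bp of the summit and score at least 6.26, the lowest left-out score (rank 5). The 7 peaks above all weaker regions scored 30.4 or more when left out, so many of these matches are much weaker. A copy centred near the summit at rank 15 reached past that window and was not counted. Outside the 10 strongest, a match was held by 5 of 40 peaks at ranks 11 to 50 (12.5%), but 4 of these 5 were near-identical copies. With copies counted once the share was 5.41% there, 5.37% at ranks 51 to 200 and 4.18% at the ranks after those, with overlapping intervals, so no fall with rank is shown. In all, 56 of 1195 peaks held a match (4.69%, at most 3.18% with shuffled positions), or 4.29% with copies counted once, against 1.59% of weaker regions matched for GC content (Fisher's exact p = 8.7e-05). Matches to the 46 bp sequence were thus commoner at optimal peaks, but most peaks held none, and the share of promoters was not matched. Shorter words from its first 10 positions were also enriched at summits. On chromosomes I to III, GGTCTCGC (other strand GCGAGACC) lay only at the summit in 42 peaks and only in the flanks in 1. On IV, V and X it gave 15 against 2, and GTCTCGCA gave 14 against 3, both past the test. These word counts did not leave out the 10 strongest peaks, and the contrast with flanks did not separate GC content.

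Ribosomal protein genes had an odds ratio of 23.6 for being targets at 500 bp and 3.80 at 250 bp. A background of promoters with any combined-list region did not remove the enrichment at 500 bp (odds ratio 9.76). Having a listed region therefore did not by itself account for it. Of the weaker regions, 29.1% lay at promoters, near the 22.9% of uniform placement. That background therefore cannot stand for promoters bound by many proteins. The shared sequence may be commoner there: 16.3% of 43 ribosomal protein gene peaks held a match against 4.25% of 1152 others (Fisher's exact p = 0.0029). This met the criterion set down beforehand, a p under 0.05, and by that criterion alone the explanation fits. Further checks were added after this result was seen, and with them the verdict was changed to open. With copies counted once the shares were 16.3% and 3.84% (Fisher's exact p = 0.0017). The excess stayed past the 0.05 threshold with ranks held fixed (7 peaks against 2.62 by chance, one-sided permutation p = 0.0119) and with a stricter score cutoff (6.98% against 1.56%, Fisher's exact p = 0.0367), but not with both changes (3 peaks against 1.33, one-sided permutation p = 0.137). At the looser cutoff 36 of the 43 peaks held no match. The 7 peaks with a match were at ranks 265 to 765. All stronger ribosomal protein gene peaks lacked one, among them those at rps-19, rps-0, rpl-3 and rpl-35 (ranks 11 to 22). Binding of unrelated proteins at the same promoters was not analysed here.

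The lack of regions at C04F5.9 could come from extra transgene copies in the control alignment, or from the gene's surroundings. In the combined list, 1.66% of protein-coding genes lay in a stretch without a region that was as long, and 1.23% and 0.62% did for the stretches in replicates 1 and 2. Counted by runs of as many neighbouring genes, 3.44% were empty in the combined list, 1.68% in replicate 1 and 2.01% in replicate 2. That is uncommon but not rare enough to decide, and the control was not analysed here, so these explanations cannot be told apart.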
